A study of Homo sapiens with 4 samples.

How the data were processed

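RNA was measured by paired-end sequencing in 4 libraries of JAR cells, an established human choriocarcinoma (placental trophoblast tumour) line. Per the labels' protocols, JAR cells were kept for 24 h with IL-2 at 100 IU/mL, either alone (group JAR, 2 libraries) or together with natural killer (NK) cells (group JAR+NK, 2 libraries). The ratio is written 5:1, and which cell type is the 5 is not stated unambiguously. Viable JAR cells were then sorted by flow cytometry with CD57-positive NK cells and dead cells gated out. NK cells that carry no CD57 are not removed by that gate as described. RNA was extracted with a miRNeasy kit and sequenced by Novogene, per the labels' protocols. The source of the NK cells is not given in the sources used here.

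The values deposited by the authors are TPM (transcript abundances scaled to a fixed sum per library) for each Ensembl transcript, 1 column per library. Per the submitters' processing notes, they come from kallisto with the genome build GRCh38. Version, transcript index, trimming and strand setting are not given in the sources used here. TPM divides out transcript length and library size, so the depth of each library is unknown and no counting interval or detection limit was computed. A value of 0 can be a failed estimate and is given as listed at 0. kallisto shares reads between similar transcripts by likelihood, so that genes with near-identical copies or overlapping exons, and polymorphic genes such as HLA, have uncertain levels.

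The deposited table held 193845 rows and 191887 distinct transcripts, whose TPM summed to 1000000 in each library. There were 1689 transcripts on more than 1 row, with equal values on each, and each was used once. TPM were summed per gene by the symbol given in the table. Of the 9542 transcripts with no symbol, 7883 were given a gene ID from GENCODE 29, and 1659 with no gene were left out (0.144 to 0.153% of the TPM). This gave 35550 genes. Protein-coding status and coordinates came from GENCODE 29 on GRCh38, which may not be the annotation the authors used. XIST and Y-linked genes were tested with the rest and are not reported.

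The comparison JAR+NK against JAR used limma's moderated test with an intensity trend on log2(TPM + 1), for genes with a mean of at least 1 TPM over the 4 libraries, with Benjamini-Hochberg adjustment at 0.05. The plan for estimated counts was not used, because the table holds TPM; the test used was the one set in advance for that case. Fold changes are on the log2(TPM + 1) scale and understate the change of low genes. Ratios of mean TPM are given as folds beside them, except where the JAR mean is under 0.5 TPM. Intervals are 95% intervals from the same fit. The self-test on simulated values for 12680 genes recovered 4%, 46%, 86% and 94% of 50 genes changed by 0.5, 1, 2 and 3 on the log2 scale, with no call of the wrong sign. In it, 6.5% of calls were unchanged genes, and with no gene changed 0 genes were called. Its noise was independent between genes, with variances drawn from the fit to these libraries. It therefore cannot show how many calls are wrong in the real data, where genes are correlated.

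A total of 25 gene lists was tested with camera (preset inter-gene correlation 0.01, then an estimated one) and with fry, with Benjamini-Hochberg adjustment over the lists. The lists covered interferon and antigen presentation, NF-kB, NK cell ligands, cell death and stress, metabolism, trophoblast types, leukocyte types, and mitochondrial and ribosomal genes. Members are called measured if their mean over the 4 libraries was at least 1 TPM. A gene near 0 in JAR is thus measured only if it was higher in JAR+NK. Measured were 24 of 40 listed interferon-gamma, 23 of 42 type I interferon, 6 of 15 class II and 17 of 50 NK cell marker genes. fry tests whether a list moves, on balance, one way, and does not compare it with other genes. The genes named were the 10 largest rises and 10 largest falls among protein-coding genes past the threshold with non-overlapping libraries and at least 10 TPM in the higher group, outside the leukocyte lists. To these were added up to 4 members of each list by adjusted p with at least 1 TPM in a group, and 21 genes fixed by name (HLA-A, HLA-B, HLA-C, HLA-E, HLA-G, B2M, STAT1, IRF1, CD274, MICA, MICB, ICAM1, CGA, CGB5, ERVW-1, GCM1, PTPRC, NKG7, GNLY, MKI67 and IFNG). Other genes named in the text were chosen after their values were seen. The comparison, test, lists, naming rule and most alternatives were fixed before the data were examined. Median-of-ratios scaling, the fit without mitochondrially encoded genes and 4 further gene lists were added afterwards.

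Alternatives were quantile normalization, upper quartile and median-of-ratios scaling, no filter or a mean of at least 5 TPM, pseudocounts 0.1 and 5, a replicate block, each library left out, protein-coding genes only, single transcripts, and a test against a 1.5-fold change. Genes of the leukocyte lists or mitochondrially encoded genes were also left out. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.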

Results

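The gene expression of sorted JAR choriocarcinoma cells was compared between cells kept for 24 h with NK cells and IL-2 (JAR+NK, 2 libraries) and cells kept with IL-2 alone (JAR, 2 libraries). The question addressed was how the transcriptome of these trophoblast tumour cells differed after contact with NK cells. Between 12438 and 12785 genes reached 1 TPM per library. The depth of the libraries is unknown, since TPM carry no read number. Over the 12680 genes tested, log2(TPM + 1) correlated across genes at 0.979 between the JAR libraries, 0.981 between the JAR+NK libraries, and 0.961 to 0.966 between groups; genes are not independent replicates. The first principal component separated the groups and held 55.0% of the variance. Nothing in the labels says that the libraries come from separate cultures, so p-values measure the spread between these libraries, which may be technical.

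In JAR+NK, 16 of 20 measured genes of MHC class I antigen presentation and 15 of 24 of the interferon-gamma response rose, and 8 of 29 of hypoxia and glycolysis fell. Camera called these lists with its preset correlation but not with an estimated one (adjusted p = 0.205, 0.205 and 0.339), and fry did not call the hypoxia list (adjusted p = 0.081). The estimated correlations were -0.050, 0.077 and 0.47, against the preset 0.01. The 16 class I genes include HLA-A, HLA-B and HLA-C, for which RNA of residual NK cells stays open. The summed NK cell markers were at 13.2 TPM in JAR and 129 TPM in JAR+NK. The largest rises included TAP1, a subunit of the peptide transporter of antigen presentation, from 17.1 ± 1.28 to 244 ± 26.6 TPM (SD, n = 2 each), and IRF1, a transcription factor induced by interferon-gamma, from 13.3 ± 3.72 to 186 ± 21.8 TPM. Among the falls, NDRG1, a stress-responsive gene, went from 139 ± 49.2 to 36.7 ± 1.89 TPM. In limma's test, 298 genes changed at an adjusted p under 0.05, of which 196 were higher and 102 lower in JAR+NK. At least 2-fold changes were found for 184 genes, 122 higher and 62 lower. All 298 changed genes had libraries that did not overlap between the groups, as had 6649 of the 12680 tested genes (52.4%). Leaving out 1 library therefore cannot reverse their sign. The genes were also picked on these same libraries, so the fits without 1 library are no independent support. Each of the 298 kept its sign and an unadjusted p under 0.05 when any 1 library was left out, but no gene passed the adjusted threshold then. The smallest adjusted p in limma was 0.0841 without JAR replicate 1, 0.106 without JAR replicate 2, 0.12 without JAR+NK replicate 1 and 0.125 without JAR+NK replicate 2. Unadjusted p under 0.05 was reached by 1877, 1388, 1817 and 1851 genes in these fits. With no filter on low values, limma also called 0 genes (2986 at an unadjusted p under 0.05, smallest adjusted p 0.0527). Testing protein-coding genes alone called 535, and testing transcripts one by one called 2 genes, PSMB10 and IRF1. With 2 libraries against 2, a permutation of single values cannot go below p = 0.333, so only the test across genes was used.

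**Figure D1:**
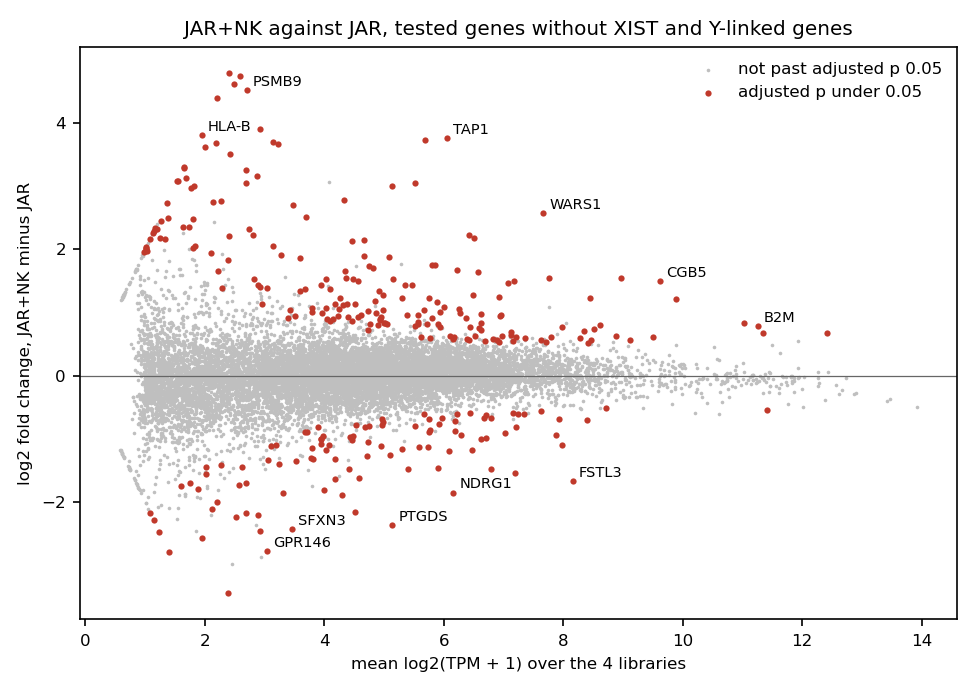
Log2 fold change (JAR+NK minus JAR, vertical axis) against mean log2(TPM + 1) over the 4 libraries (horizontal axis), 1 point per tested gene outside XIST and the Y-linked genes. Red points are the genes past an adjusted p of 0.05 in limma; TAP1 stands at 3.76, WARS1 at 2.58, NDRG1 at -1.85 and GPR146 at -2.78.

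The 10 largest rises under the naming rule were PLAAT4, TMSB4X, PSMB9, APOL6, HLA-B, TAP1, IRF1, IL32, HLA-A and HEG1, with log2 fold changes of 3.66 to 4.79. APOL6, an apolipoprotein L family member, rose by 3.91 (SE 0.19, adjusted p = 0.000496 in limma), 29.9-fold in mean TPM. HEG1, a transmembrane protein of endothelial junctions, rose 20.1-fold and IL32, a cytokine gene, 19.7-fold. TMSB4X, which encodes the actin-binding thymosin beta 4, was listed at 0 in both JAR libraries and at 18.4 and 38.5 TPM in the JAR+NK libraries. It is abundant in leukocytes, and GZMB, a granule gene of NK cells, was likewise listed at 0 in both JAR libraries and at 15.4 and 26.3 TPM in the JAR+NK libraries. The summed NK cell markers were at 13.2 ± 1.23 TPM in JAR and 129 ± 19.6 TPM in JAR+NK beside these rises. The 10 largest falls were GPR146, TNNT3, SFXN3, PTGDS, PNCK, S100A4, CASP14, ZNF395, BNIP3L and NDRG1, with log2 fold changes of -2.78 to -1.85. PTGDS, which encodes prostaglandin D2 synthase, fell from 79.9 ± 19.5 to 14.8 ± 4.10 TPM (adjusted p = 0.0056 in limma). SFXN3, a mitochondrial carrier gene, fell from 24.9 ± 5.58 to 3.79 ± 0.861 TPM (adjusted p = 0.0054 in limma). GPR146, a G protein-coupled receptor gene, had 13.6 and 30.7 TPM in the JAR libraries and 2.17 and 2.11 TPM in the JAR+NK libraries.

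In GENCODE 29 on GRCh38, TAP1 lies on chromosome 6 from 32845209 to 32853978 on the minus strand. PSMB9 lies on chromosome 6 from 32844136 to 32859585 on the plus strand and spans TAP1. IRF1 lies on chromosome 5 from 132481609 to 132490798, PTGDS on chromosome 9 from 136975092 to 136981742, and NDRG1 on chromosome 8 from 133237171 to 133302022. Each is annotated as protein-coding, and the values are sums over all transcripts of the gene. Exons of PSMB9, TAP1, IRF1, PTGDS and GPR146 overlap exons of other annotated genes, and 58 of the 120 named genes with a position have such an overlap, among them KRT8 and KRT18 (with each other) and DTX3L (with PARP9). Without a stated strand setting, part of such reads cannot be assigned with certainty.

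MHC class I presentation had the highest median of the 25 lists. Of its 20 measured members, 16 rose, none fell and 4 did not pass (16 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 2.17. TAP2, the partner of TAP1, rose by 3.05 (SE 0.15, 8.71-fold in TPM). TAPBP, which encodes tapasin, rose by 3.01 (SE 0.14, 8.72-fold). PSMB9, an immunoproteasome subunit, was at 0.465 and 0.255 TPM in the JAR libraries and at 27.4 and 32.9 TPM in the JAR+NK libraries. B2M, the light chain of class I molecules, rose from 1859 ± 157 to 3224 ± 345 TPM, and HLA-E, a non-classical class I gene, from 78.2 ± 5.23 to 187 ± 5.28 TPM. HLA-F, CANX, CALR and PDIA3 did not pass, and HLA-G was listed at 0 in all 4 libraries. The list was called by camera (adjusted p = 6.32e-19; adjusted p = 0.205 with an estimated correlation) and by fry (adjusted p = 2.34e-05). None of the camera calls on the 25 lists held after adjustment with an estimated correlation, which here rests on 2 residual degrees of freedom. The estimate was -0.050 for class I and 0.0013 for type I interferon genes, both under the preset 0.01. A higher correlation is thus not what removed these 2 calls. The estimate lay above the preset for other lists, at 0.077 for interferon-gamma, 0.47 for hypoxia, 0.46 for immediate early, 0.58 for mitochondrial and 0.78 for ribosomal genes.

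The classical genes HLA-A, HLA-B and HLA-C passed the test from JAR levels near 0. HLA-A was at 0.305 and 0.230 TPM in the JAR libraries and at 12 and 19.5 TPM in the JAR+NK libraries. HLA-B was at 0 and 0.0641 TPM, then at 25 and 7.02 TPM, and HLA-C at 0.141 and 0.350 TPM, then at 9.62 and 8.27 TPM. These genes share sequence and are highly polymorphic, so the split between them is uncertain. Genes of NK cells were higher in the same libraries: the summed TPM of 50 NK cell marker genes was 13.2 ± 1.23 in JAR and 129 ± 19.6 in JAR+NK.

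Interferon-gamma response genes had 15 of 24 measured members higher, 0 lower and 9 not passing (19 higher adjusted over the list alone), with a median log2 fold change of 1.42. Of the 40 genes listed, those under the filter included CXCL9, GBP4, GBP5 and CXCL10, at 0.0216, 0.521, 1.13 and 1.40 TPM in JAR+NK. WARS1, a tRNA synthetase induced by interferon-gamma, rose from 82.0 ± 7.59 to 494 ± 64.6 TPM, and STAT1, the transcription factor activated by interferons, from 23.8 ± 1.45 to 65.9 ± 1.82 TPM. PLAAT4 was at 0 and 0.345 TPM in the JAR libraries and at 25.2 and 36.2 TPM in the JAR+NK libraries. JAK2, IRF8 and SECTM1 did not pass. Camera gave an adjusted p of 1.66e-19 (adjusted p = 0.205 with an estimated correlation) and fry 0.00634. Type I interferon response genes had 8 of 23 measured members higher and 0 lower (13 higher adjusted over the list alone), with a median of 1.18. IFITM3, an antiviral membrane protein, rose 7.83-fold (log2 2.79, SE 0.19), LGALS3BP 3.95-fold and ISG15, a ubiquitin-like modifier, 2.87-fold. DTX3L went from 0.141 ± 0.00159 to 13.1 ± 0.297 TPM. MX1, XAF1, USP18 and HERC6 did not pass, with log2 fold changes of -0.17, 0.17, 0.06 and -0.02. Camera gave an adjusted p of 1.57e-10 (adjusted p = 0.205 with an estimated correlation), and fry 0.0018. IFNG itself was listed at 0 in both JAR libraries and at 0.874 and 1.96 TPM in the JAR+NK libraries, beside the NK marker sum of 129 TPM. CD274, which encodes PD-L1, was at 0, 0, 0 and 0.0478 TPM.

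MHC class II presentation had 2 of 6 measured members higher (2 adjusted over the list alone): CD74, the invariant chain, at 0.75 ± 0.30 and 6.10 ± 1.19 TPM, and IFI30, a lysosomal thiol reductase, up 1.54-fold. HLA-DMA and HLA-DPB1 did not pass. CD74 is abundant in some leukocytes, and the NK marker sum rose from 13.2 to 129 TPM in the same libraries, with NKG7 at 0 and 0, then 6.46 and 8.56 TPM. IFI30 lost its call under upper quartile (adjusted p = 0.0696 in limma) and median-of-ratios scaling (0.0672). The median was 0.48 and the camera adjusted p 0.0457 (adjusted p = 0.339 with an estimated correlation, 0.053 with the replicate number as a block). It was 0.0817 without JAR replicate 1, 0.0645 without JAR+NK replicate 2, 0.0528 under median-of-ratios scaling and 0.41 at a mean of at least 5 TPM.

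**Figure D2:**
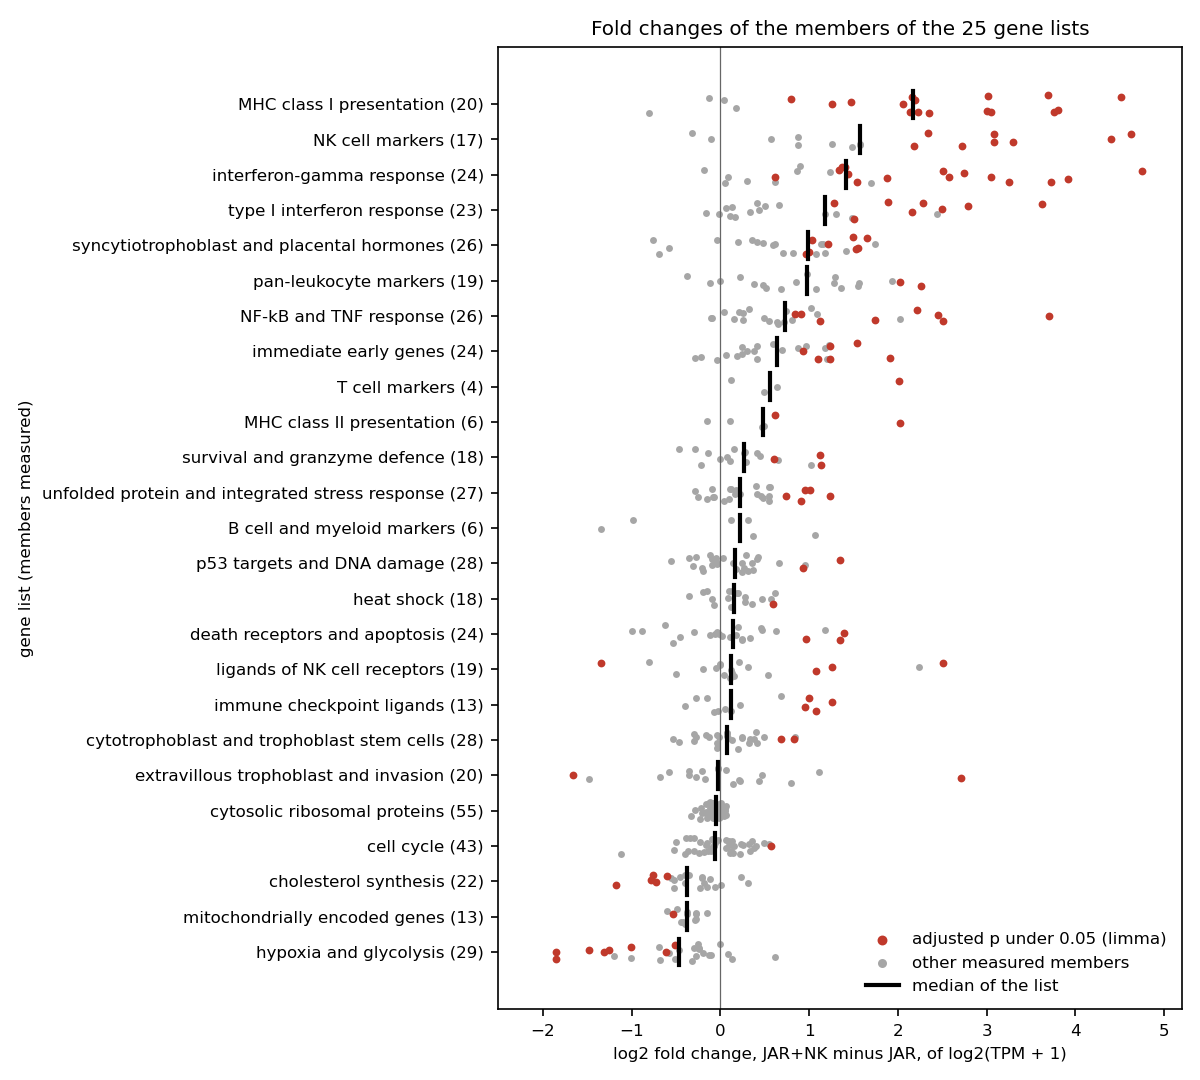
Log2 fold changes (JAR+NK minus JAR, horizontal axis) of the measured members of each of the 25 gene lists (rows), 1 point per gene, red where the adjusted p in limma was under 0.05, with a black bar at each list's median. The medians run from 2.17 for MHC class I presentation to -0.47 for hypoxia and glycolysis.

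Of 26 measured genes of the NF-kB and TNF response, 8 rose, 0 fell and 18 did not pass (15 higher adjusted over the list alone), with a median of 0.73. ICAM1, an adhesion molecule that is also a member of the interferon-gamma and NK ligand lists, rose 6.69-fold to 30.1 ± 3.89 TPM. NFKB2, an NF-kB subunit, rose 3.56-fold (log2 1.74, SE 0.18) and RELB, its usual partner, 7.24-fold. Camera gave an adjusted p of 6.77e-11 (adjusted p = 0.257 with an estimated correlation). fry gave 0.0145. Immediate early genes had 6 of 24 higher and 0 lower (15 higher adjusted over the list alone). DUSP5, a phosphatase of the ERK pathway, rose 3.05-fold, MYC 2.17-fold and KLF10 1.96-fold. The list's median was 0.64, with a camera adjusted p of 1.46e-08 (adjusted p = 0.339 with an estimated correlation). fry did not call it (0.1001). In the unfolded protein and integrated stress response list, 5 of 27 were higher and 0 lower (12 higher and 2 lower adjusted over the list alone). ATF3, a stress-induced transcription factor, rose 2.40-fold, TRIB3 2.05-fold, ASNS, which makes asparagine, 1.96-fold and the amino acid transporter subunit SLC3A2 1.67-fold. The median was 0.22 and the camera adjusted p 2.94e-05 (adjusted p = 0.339 with an estimated correlation). fry gave 0.0679. The NK marker sum of 129 TPM in JAR+NK stood beside these rises too.

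Ligands of NK cell receptors were not called as a list (median 0.12, camera adjusted p = 0.115), but were called upwards with no filter (0.0205). Of 19 measured, 3 rose and 1 fell (4 higher and 1 lower adjusted over the list alone). HLA-E, ligand of NKG2A, ICAM1 and PVR, ligand of DNAM-1, which was up 2.25-fold, were higher. NECTIN4 was lower, at 17.4 ± 2.88 and 6.35 ± 1.94 TPM. MICA and MICB, ligands of NKG2D, did not pass: MICA was at 2.90 ± 2.50 and 3.31 ± 0.378 TPM, and MICB at 15.4 ± 3.07 and 15.5 ± 4.0 TPM. Among immune checkpoint ligands, 4 of 13 rose and 0 fell (4 adjusted over the list alone): HLA-E, PVR, VSIR, which encodes VISTA (2.11-fold), and TGFB1 (2.06-fold). The median was 0.12, with a camera adjusted p of 0.0344 (adjusted p = 0.339 with an estimated correlation, 0.0525 with the replicate number as a block). The NK ligand list reached 0.0493 without JAR replicate 2, and the checkpoint list gave 0.232 without JAR replicate 1 and 0.108 without JAR+NK replicate 2. The NK marker sum was 13.2 TPM in JAR and 129 TPM in JAR+NK beside the rises of both lists.

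A minority of the genes of cell death, damage and proliferation passed, where 298 of 12680 tested genes passed in all. The self-test called 4% and 46% of genes changed by 0.5 and 1 on the log2 scale. A small number of calls therefore does not show that little changed. Death receptor and apoptosis genes had 3 of 24 higher and 0 lower (6 higher and 1 lower adjusted over the list alone; median 0.14, camera adjusted p = 0.123, and 0.0309 with no filter). PMAIP1, which encodes the pro-apoptotic NOXA, rose 2.62-fold, GSDMD, a pore-forming gasdermin, 2.01-fold and the executioner caspase CASP7 3.46-fold. Survival and granzyme defence genes had 3 of 18 higher and 0 lower (4 higher adjusted over the list alone; median 0.27). These were TNFAIP3 (2.29-fold), CD59 (2.29-fold), which blocks complement lysis, and MCL1 (1.53-fold). SERPINB9, the granzyme B inhibitor, was at 59.8 and 73.1 TPM and did not pass. Camera gave this list an adjusted p of 0.0344 (adjusted p = 0.392 with an estimated correlation), 0.232 without JAR replicate 1, 0.181 without JAR+NK replicate 2, 0.0537 under quantile normalization and 0.143 at a mean of at least 5 TPM, and fry gave 0.0661. The p53 target and DNA damage list had 2 of 28 higher, PMAIP1 and PLK3, and 0 lower (7 higher and 1 lower adjusted over the list alone; median 0.16, camera adjusted p = 0.0665, 0.0199 with no filter and 0.0248 without JAR+NK replicate 2). PLK3 did not pass without mitochondrially encoded genes (adjusted p = 0.057 in limma), which left 1 of 28 higher. Of 43 cell cycle genes, RRM2 alone passed, up 1.49-fold (1 higher and 2 lower adjusted over the list alone; median -0.06, camera adjusted p = 0.569). RRM2 did not pass under upper quartile and median-of-ratios scaling (adjusted p = 0.0943 and 0.0919 in limma), where 1 other member was lower, nor without mitochondrially encoded genes (0.0552), and at a mean of at least 5 TPM 2 members were lower beside it. MKI67, a proliferation marker, was at 35.6 ± 3.10 and 33.5 ± 4.19 TPM (log2 fold change -0.09, 95% interval -0.43 to 0.25). Of 18 heat shock genes, DNAJA1 alone passed, up 1.51-fold (2 higher adjusted over the list alone; median 0.16), and not under upper quartile and median-of-ratios scaling (adjusted p = 0.0613 and 0.0592 in limma). The camera adjusted p of that list was 0.0344 (adjusted p = 0.435 with an estimated correlation), and 0.0508, 0.0735 and 0.0635 without JAR replicate 1, JAR replicate 2 and JAR+NK replicate 1. It was 0.0593 and 0.0568 under upper quartile and median-of-ratios scaling and 0.051 at a mean of at least 5 TPM, and fry gave 0.121. Beside the rises in these lists, the NK marker sum was 13.2 TPM in JAR and 129 TPM in JAR+NK.

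Of 29 measured hypoxia and glycolysis genes, 8 fell in JAR+NK, none rose and 21 did not pass (19 lower and 1 higher adjusted over the list alone), with a median of -0.47. BNIP3, a mitophagy receptor induced by hypoxia, went from 188 ± 57.0 to 65.3 ± 2.19 TPM (log2 -1.48, SE 0.19). Its relative BNIP3L went from 17.7 ± 0.139 to 4.33 ± 1.67 TPM and PFKFB4, a regulator of glycolysis, from 52.4 ± 11.8 to 21.2 ± 2.36 TPM. VEGFA, a hypoxia target, did not pass, at 70.6 and 77.6 TPM. Camera gave an adjusted p of 4.49e-11 (adjusted p = 0.339 with an estimated correlation) and fry 0.081. Cholesterol synthesis genes had 5 of 22 lower and 0 higher (9 lower adjusted over the list alone), with a median of -0.38. TM7SF2, a sterol reductase, fell to 0.42 of its JAR level (log2 -1.17, SE 0.16). MSMO1 was at 77.8 ± 3.78 and 45.4 ± 1.82 TPM, SQLE, the squalene epoxidase, at 92.6 ± 6.13 and 55.8 ± 3.27 TPM, and STARD4 at 39.8 ± 3.48 and 22.8 ± 2.65 TPM. Camera gave 7.24e-08 (adjusted p = 0.257 with an estimated correlation) and fry 0.027.

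Mitochondrially encoded genes took 9.24 and 8.37% of the TPM in the JAR libraries and 7.19 and 6.39% in the JAR+NK libraries. Of 13 genes, MT-ND6 alone passed, at 3264 ± 48.2 and 2257 ± 125 TPM (9 lower adjusted over the list alone). It did not pass under quantile, upper quartile and median-of-ratios scaling (adjusted p = 0.0651, 0.0762 and 0.0792 in limma), where no other member did, and 5 members were lower with the replicate number as a block. The median was -0.38, with a camera adjusted p of 1.8e-07 (adjusted p = 0.339 with an estimated correlation) and 0.118 in fry. No cytosolic ribosomal protein gene passed among 55 (0 adjusted over the list alone). Their median was -0.05 and the camera adjusted p 0.0158 (adjusted p = 0.725 with an estimated correlation). In fry the adjusted p was 0.593. The camera value was 0.188 under quantile normalization, 0.748 without JAR replicate 2, and 0.67 with the opposite direction without JAR+NK replicate 1.

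In the list of syncytiotrophoblast and placental hormone genes, 8 of 26 measured members rose, 0 fell and 18 did not pass (18 higher and 1 lower adjusted over the list alone), with a median of 0.98. The count was 14 of 22 at a mean of at least 5 TPM and 16 of 26 with the replicate number as a block. CGA and CGB5 each gained more TPM than the whole NK marker sum of 129 TPM in JAR+NK. CGA, the alpha subunit of chorionic gonadotropin, rose from 635 ± 198 to 1445 ± 271 TPM, and CGB5, a beta subunit gene, from 481 ± 148 to 1333 ± 194 TPM. CGB8 rose 2.88-fold; the CGB genes are near-identical copies, so their split is uncertain. CYP19A1, the aromatase gene, rose 3.0-fold (log2 1.53, SE 0.15) and HSD17B1, which makes estradiol, 1.99-fold. GCM1, a transcription factor of syncytiotrophoblast formation, was at 18.6 ± 3.36 and 33.3 ± 0.774 TPM and did not pass (adjusted p = 0.054 in limma), and ERVW-1, the syncytin-1 gene, was at 267 ± 24.5 and 262 ± 41.4 TPM. Camera gave the list an adjusted p of 4.31e-10 (adjusted p = 0.339 with an estimated correlation) and fry 0.0722.

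Camera did not call the other trophoblast lists. Cytotrophoblast and stem cell genes had 2 of 28 higher and 0 lower (7 higher and 1 lower adjusted over the list alone; median 0.08, camera adjusted p = 0.0737, 0.0374 with no filter, 0.0368 without JAR replicate 2 and 0.0422 without JAR+NK replicate 2). The keratin genes KRT18 and KRT8 rose 1.78-fold and 1.61-fold, to 2797 ± 367 and 3302 ± 232 TPM, but KRT8 did not pass under upper quartile and median-of-ratios scaling (adjusted p = 0.0589 and 0.0564 in limma). Extravillous trophoblast and invasion genes had 1 of 20 higher and 1 lower (5 higher and 3 lower adjusted over the list alone; median -0.02, mean 0.02, camera adjusted p = 0.766). SERPINE1, a plasminogen activator inhibitor, rose 8.06-fold (log2 2.71, SE 0.21), and FSTL3, an activin-binding protein, fell from 511 ± 91.6 to 161 ± 26.5 TPM.

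**Figure D3:**
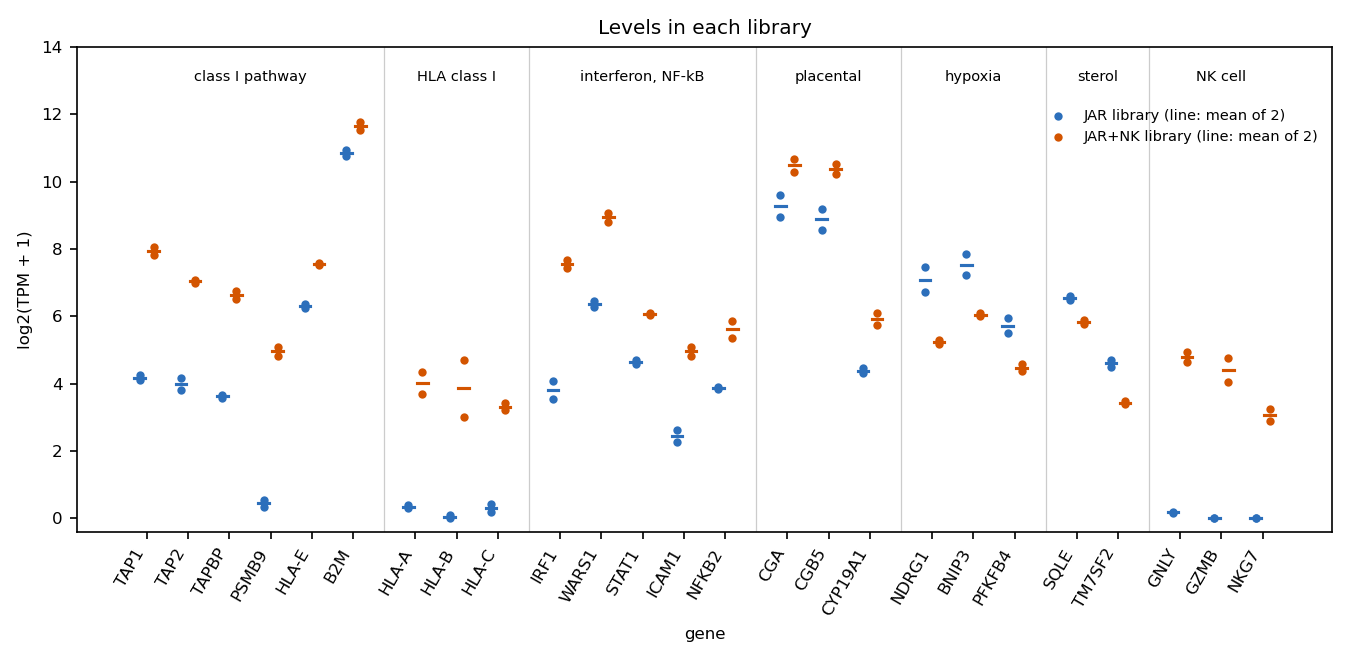
Level of selected genes as log2(TPM + 1) (vertical axis) in each library, with JAR in blue, JAR+NK in orange and a line at the mean of the 2 libraries of a group. For each gene shown the JAR+NK libraries lie on 1 side of the JAR libraries; HLA-B spreads from 7.02 to 25 TPM within JAR+NK.

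RNA of leukocyte genes was present in the sorted JAR+NK libraries at low levels. GNLY and GZMB, cytotoxic granule genes of NK cells, were at 0.136 and 0.112 TPM (GNLY) and 0 and 0 TPM (GZMB) in the JAR libraries, against 23.8 and 29.8 TPM (GNLY) and 15.4 and 26.3 TPM (GZMB) in the JAR+NK libraries. NKG7 was listed at 0 in both JAR libraries and at 6.46 and 8.56 TPM in JAR+NK. Of the 50 NK cell markers, 26 were listed at 0 in both JAR libraries, and 22 of these were above 0 in both JAR+NK libraries. Among 17 measured markers, 8 rose and 0 fell (11 higher adjusted over the list alone; median 1.58, camera adjusted p = 6.74e-11, adjusted p = 0.257 with an estimated correlation). The summed pan-leukocyte markers were 348 ± 5.28 TPM in JAR and 399 ± 34.1 TPM in JAR+NK, with 2 of 19 higher, RAC2 and LCP2 (9 higher adjusted over the list alone; median 0.98, camera adjusted p = 2.61e-05, adjusted p = 0.339 with an estimated correlation). LCP2 did not pass under the 3 scalings or without mitochondrially encoded genes (adjusted p = 0.0509 to 0.0545 in limma), and the list was not called by fry (adjusted p = 0.0661) or at a mean of at least 5 TPM (0.251 in camera). PTPRC, which encodes CD45, was at 0.636 ± 0.0797 and 3.38 ± 1.81 TPM and did not pass. T cell markers summed to 11.6 ± 1.35 and 23.7 ± 2.49 TPM. Of their 4 measured members, TRDC rose (1 adjusted over the list alone; median 0.56, camera adjusted p = 0.0457, adjusted p = 0.339 with an estimated correlation), and the list gave 0.0663 without JAR replicate 1 and 0.0635 without JAR+NK replicate 1. TRDC did not pass under quantile normalization (adjusted p = 0.0511 in limma) or without mitochondrially encoded genes. With the replicate number as a block, camera gave the T cell list an adjusted p of 0.0525. B cell and myeloid markers summed to 31.5 ± 7.38 and 37.9 ± 2.07 TPM. None of 6 passed (1 higher adjusted over the list alone), and their median of 0.22 and mean of -0.08 differed in sign (camera adjusted p = 0.868).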

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

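Median-of-ratios scaling and the fit without mitochondrially encoded genes were chosen after the data were seen. Against 298 changed genes, separate fits called 306, 328, 319 and 256 under quantile, upper quartile and median-of-ratios scaling and without mitochondrially encoded genes, of which 262, 268, 262 and 254 were among the 298. Pseudocounts 0.1 and 5 called 269 and 260 (269 and 256 shared), a mean of at least 5 TPM 401 (255 shared), and the fit without leukocyte list genes 277, each among the 298. The share that was higher stayed between 58.2 and 65.8% under the 3 scalings and the deposited scale. No filter gave 0 (21187 genes tested, 2986 at unadjusted p under 0.05), each library left out 0 (1388 to 1877 at unadjusted p under 0.05; the lone library is assumed to vary like the other group), protein-coding genes only 535 and single transcripts 2 (PSMB10 and IRF1; 48525 transcripts). For the 184 changes of at least 2-fold, no filter and each library left out gave 0, pseudocount 5 gave 120, the test against 1.5-fold 57 and single transcripts 2. Fewer samples, and more or fewer features tested, are part of these settings. In the main fit each gene had 2 residual degrees of freedom, and limma added 4.82 borrowed across genes. The borrowed number was 2.27 with no filter, 5.85 at a mean of at least 5 TPM, 6.12 for protein-coding genes only and 6.31 with the replicate block. Under the 3 scalings it was 4.38 to 4.84. Whether it sets these counts was not tested, nor were other causes. The values are TPM, so the planned tests for counts were not run. With the replicate number as a block, 694 and 283 genes were called. The deviations of same-numbered libraries correlated at 0.0784 over 2 pairs. The second principal component (24.7% of the variance) set replicate 1 apart from replicate 2 in both groups. Its scores were 16.3 and -13.9 in JAR and 19.2 and -21.6 in JAR+NK. With 2 pairs, these values do not decide whether same-numbered libraries were paired, and the block is no evidence of it. None of the 117 named genes reversed a call; 442 of their results under an alternative lost a call, 79 of these in each fit without 1 library, and 37 gained one.

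Gene list calls, as camera adjusted p, changed as follows. Quantile normalization gave 0.0537 for survival and 0.188 for ribosomal genes, upper quartile scaling 0.0593 for heat shock, and median-of-ratios scaling 0.0528 for class II and 0.0568 for heat shock. No filter gave 0.0205 for NK ligands, 0.0309 for death receptors, 0.0199 for p53 and 0.0374 for cytotrophoblast. A mean of at least 5 TPM gave 0.41 for class II, 0.143 for survival, 0.051 for heat shock and 0.251 for pan-leukocyte genes. The block gave 0.053 for class II and 0.0525 for checkpoint ligands and T cell markers. Without 1 library, the ranges were 0.0281 to 0.0817 for class II, 0.018 to 0.232 for checkpoint ligands, 0.00404 to 0.232 for survival, 0.0384 to 0.0735 for heat shock, 0.0422 to 0.0663 for T cell markers, 0.0493 to 0.424 for NK ligands, 0.0368 to 0.415 for cytotrophoblast, 0.0248 to 0.267 for p53 and 6.04e-08 to 0.748 for ribosomal genes, which turned upwards without JAR+NK replicate 1 (0.67). The cause was not tested. In lists with 1 or 2 calls, MT-ND6 lost its call under the 3 scalings, RRM2, DNAJA1, KRT8 and IFI30 under upper quartile and median-of-ratios scaling, LCP2 under all 3 (highest adjusted p = 0.0545 in limma) and TRDC under quantile normalization (0.0511). Without mitochondrially encoded genes, RRM2, LCP2, TRDC and PLK3 lost theirs.

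With an estimated correlation the adjusted p was 0.205 for the interferon-gamma, type I interferon and class I lists, 0.257 for NF-kB, cholesterol and NK markers, 0.339 for class II, checkpoint, unfolded protein, immediate early, hypoxia, syncytiotrophoblast, pan-leukocyte, T cell and mitochondrial genes, 0.392 for survival, 0.435 for heat shock and 0.725 for ribosomal genes. fry gave 0.0661 for survival and pan-leukocyte genes, 0.0679 for unfolded protein, 0.1001 for immediate early, 0.121 for heat shock, 0.081 for hypoxia, 0.0722 for syncytiotrophoblast, 0.118 for mitochondrial and 0.593 for ribosomal genes. The NK marker gain of 116 TPM was 93.2 TPM with a narrower list and 102 to 130 TPM without 1 library. The mean replicate correlation of 0.98 was 0.706 over the 500 most variable genes. Depth is unknown and limits low genes by an unknown amount.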

Other observations

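The 4 gene lists of complement, interferon receptors and signalling, the constitutive proteasome core and further hypoxia-induced genes were added after the results above were seen. The expected outcome was stated before these lists were tested. Some members had been seen already: CD59 in the survival list, and STAT1, SOCS1 and SOCS3 in the interferon-gamma list. The complement and signalling lists are therefore not independent of the earlier ones. The tests on residual NK cell RNA, the TPM scale, HLA alleles, dilution and single JAR libraries were chosen after the results they measure were seen.

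Of 14 measured complement genes, several of which are induced by interferon-gamma, 3 rose in JAR+NK, 0 fell and 11 did not pass (6 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 0.47. CLU, which encodes clusterin, rose by 1.76 (SE 0.11), from 29.4 to 102 TPM, C4A went from 0.842 to 11.6 TPM, and CD59 rose by 1.14. C4B, C1S and CFB, at 1.65, 1.36 and 0.87, did not pass, and C4A and C4B are near-identical copies whose split is uncertain. Camera gave an adjusted p of 0.00328 (adjusted p = 0.325 with an estimated correlation) and fry 0.0208. In the same libraries, the NK marker sum was 13.2 TPM in JAR and 129 TPM in JAR+NK. In a list of 19 measured interferon receptor and signalling genes, STAT1, STAT3, SOCS3 and SOCS1 rose and none fell (5 higher adjusted over the list alone; median 0.24, camera adjusted p = 0.0434, adjusted p = 0.331 with an estimated correlation, 0.0657 in fry). STAT1, SOCS3 and SOCS1 are also members of the interferon-gamma list, so this list in part repeats that result. The hypothesis that the receptor chains rose with their targets was left undecided: IFNGR1, IFNAR2, IFNAR1 and IFNGR2 had log2 fold changes of 0.49, 0.48, -0.30 and -0.55. Their median of 0.0871 lies under the bound of 0.25 stated beforehand for no rise. The outcome was left undecided because the members go both ways (SD 0.54). That condition on the spread was not part of the bound stated beforehand.

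The immunoproteasome subunits PSMB8, PSMB9 and PSMB10 rose by 2.16, 4.52 and 2.19 on the log2 scale. The hypothesis that the whole proteasome core rose with them was tested on the 14 constitutive core subunits, whose median was 0.0932 (SD over subunits 0.18, highest 0.50), far below those values. None of them passed the test (2 higher adjusted over the list alone). Camera with the preset correlation placed them upwards (adjusted p = 0.0326; adjusted p = 0.591 with an estimated correlation, 0.242 in fry), so a small shift stays open.

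The first pattern weighed is the rise of class I presentation and interferon-gamma response genes. RNA of residual NK cells was tested on the 28 changed members outside the leukocyte lists and outside HLA-A, HLA-B and HLA-C. They gained 3376 TPM in sum, 20.27 times the 167 TPM gained by the NK cell and pan-leukocyte markers, and 12.1 times without B2M; 17 of the 28 gained more than the 26.7 TPM of the marker with the highest gain. Residual NK RNA as the whole source of the summed gain is argued against, although IFNG and a part of low members may come from it. Taken singly, leukocyte genes stood at 26.8 (GNLY), 28.5 (TMSB4X) and 3.38 TPM (PTPRC) in JAR+NK. TMSB4X, outside the marker lists and listed at 0 in JAR, also exceeds the 26.7 TPM. Members at similar levels, such as APOL6 at 28.3, PSMB9 at 30.2 and ICAM1 at 30.1 TPM, are not separated from NK RNA by level alone. A shift of the TPM scale would move genes in general, but the median log2 fold change of all 12680 tested genes was 0.024, against 2.20 for these members. Such a shift is therefore argued against as well. The members' median stayed at 2.163 or above under quantile and median-of-ratios scaling. With the median of all genes near 0, rescaling could move it little, so this adds no further support. A response of JAR cells to the co-culture remains as a hypothesis that was not tested. Only cells viable after 24 h were sorted, so a change within cells cannot be told from a change in which cells were left. These libraries also hold no condition that separates cytokine from contact.

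The second pattern is HLA-A, HLA-B and HLA-C, listed near 0 in JAR and at 46.6 and 34.8 TPM in sum in JAR+NK replicates 1 and 2, where B2M and the TAP genes were expressed in JAR already. Here residual NK RNA stays open: the ratio of the sums, replicate 2 over replicate 1, was 0.746, inside the range of 0.606 to 2.18 over 6 NK markers listed at 0 in JAR, though only CCL4 lay below it. A mismatch between alleles and the transcript reference also stays open. The log2 ratio between the libraries ranged over 2.537 among the 3 genes, against 0.641 among 13 other changed class I genes. A mismatch shared by both libraries would largely cancel in such a ratio, so this range does not decide it. Induction in JAR cells is another possibility that these values do not exclude.

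The third pattern is the lower level of hypoxia and glycolysis genes, whose median of -0.47 would need 27.6% of the RNA to come from other cells if dilution were its source. At that share GNLY, the leukocyte marker with the highest gain, would stand at 96.77 TPM in those cells, GZMB at 75.5 and PTPRC at 9.94 TPM. Such levels are low for genes abundant in NK cells and leukocytes (KRT8, the highest trophoblast list gene, had 2055 TPM in JAR). No NK cell library was measured, so the level expected in those cells is assumed. On that assumption, dilution by leukocyte RNA as the whole source is argued against. Of 74 trophoblast list genes, 65 lay above the hypoxia median and 9 below (median 0.23, SD 0.74). Dilution alone would have lowered those that leukocytes lack. These genes may have changed themselves, so they do not decide it. A single JAR library is argued against, since the list's median was -0.3758 without JAR replicate 2 and -0.52 without JAR replicate 1. A wider fall was tested on 25 further hypoxia-induced genes, of which ANKZF1 fell, none rose (8 lower adjusted over the list alone) and the median was -0.39, with a camera adjusted p of 1.592e-06 (adjusted p = 0.331 with an estimated correlation, 0.0926 in fry). A difference in oxygen or cell density between the cultures, or a response to NK cells, may underlie it; neither was measured, and both stay open.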
